A study of Homo sapiens with 6 samples.

How the data were processed

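Total RNA was sequenced from C4-2 cells grown in RPMI medium with fetal bovine serum, with 3 libraries of the vector line and 3 of the CDK12 knockout line. Groups and replicate numbers come from the sample titles. Per the labels' protocols, libraries were made with a SMARTer kit after RNeasy extraction. FastQC, STAR and the GRCh38 genome are named per the submitters' processing notes, and their versions and the annotation release are not given in the sources used here.

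Each deposited file holds whole-number read counts per gene as the authors made them, not normalised, in the layout of STAR's gene counts: 62696 gene rows after 4 summary rows, with 1 unstranded and 2 stranded columns of counts. The 2 stranded columns had ratios of 1.02 to 1.04 in their sums, so the unstranded column was used, and reads of a gene and its antisense partner cannot be told apart. Reads in more than 1 gene and reads mapping to several places are outside the gene rows, which lowers overlapping genes, paralogs and genes with close pseudogenes. The 4 summary rows stayed out of library sizes and tests. In the vector and knockout libraries they were 11.3 ± 0.255% and 12.9 ± 1.26% ambiguous, 6.93 ± 0.715% and 5.06 ± 1.30% outside genes, 7.85 ± 1.08% and 7.76 ± 1.15% multimapping and 5.39 ± 0.135% and 4.51 ± 0.654% unmapped (mean ± SD of the percent of all reads, n = 3 each).

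Total reads were 25879375, 25414939 and 24660798 in vector libraries 1 to 3 and 29207499, 30732841 and 26357250 in knockout libraries 1 to 3. At this depth the 95% binomial interval (Wilson score) of a share of reads is at most 0.0125 percentage points to either side. It covers counting error only, and PCR reads are not independent molecules. A gene at 0 counts over a group was set to 3 counts over that group for a lower bound on its fold. Chi-square per degree of freedom between libraries of one group was 3.29 or more over genes with at least 20 counts, so no 2 files agreed within sampling noise, which does not show that the libraries came from separate RNA or cultures.

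Gene names were taken by unversioned identifier from a name table (62672 of 62696 matched). Coordinates, biotype, gene span, transcript length and GC content come from GENCODE 29 on GRCh38, which may differ from the annotation behind the counts, and 15250 of 15783 tested genes (96.6%) matched it.

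Counts were analysed in R 4.3.3 with edgeR 4.0.16 (filterByExpr, TMM factors, robust quasi-likelihood fit and test, no block) on all 6 libraries, with Benjamini-Hochberg adjustment and a threshold of 0.05. SE of a log2 fold change is its size divided by the square root of the F statistic. CPM are counts scaled to a common library size with TMM factors, and log2 CPM used a prior count of 2. DESeq2 1.42.0 and limma 3.58.1 (voom) were alternatives. The 30 gene lists, with 841 symbols, were fixed before the data were examined, as were the tests, the rule for named genes and all alternatives but those said below to be added. Lists were tested with limma's camera on log2 CPM at a correlation of 0.01, adjusted over the 30 lists, and again with the correlation estimated per list. At the preset correlation 8 lists passed with all libraries and 8 without knockout library 2, and with an estimated correlation 0 and 0 passed. The fry test, which asks whether a list's genes move on balance one way and does not compare them with other genes, gave 8 lists with all libraries and 12 without knockout library 2. For gene length, Spearman's rho across genes described the trend, and an exact permutation over libraries tested it.

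Named genes are CDK12, CDK13 and CCNK, then the 12 largest rises and 12 largest falls among protein-coding genes with adjusted p under 0.05, a mean of at least 5 CPM and group CPM ranges that do not overlap, and from each list described up to 4 members with the smallest adjusted p. Sex-linked marker genes were left out of that rule, and some genes that meet it are not reported here. Of all tested genes 6214 (39.4%) had groups that do not overlap, where chance gives 10%.

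Counts were simulated with the means, library sizes and dispersions of all 6 libraries (15783 genes, 200 changed 2-fold or 4-fold, and a planted list of 30 with a smaller rise). Of the 2-fold changes 32.0% and of the 4-fold changes 86.0% were recovered. With the settings of the 5 libraries without knockout library 2 (16339 genes) 82.0% and 97.0% were recovered. Each simulated gene had the same dispersion in every library. The simulation therefore held no library that stands apart as knockout library 2 does, and the recovery with all 6 libraries may differ from that in the data. Alternatives were other scaling factors, other filters, DESeq2, limma-voom, a replicate block, stricter thresholds, exonic length, an estimated list correlation and leaving out each library. Added after the data were seen were a correction of each library for its trend over transcript length and GC content (splines with 5 degrees of freedom), the same without knockout library 2, and voom with sample weights.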

Results

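C4-2 is a human castration-resistant prostate cancer cell line. The series asked how loss of CDK12 affects such cells. CDK12 is a kinase that, with its partner cyclin K (CCNK), phosphorylates RNA polymerase II and is known for its role in the transcription of long genes and of DNA repair genes. Bulk RNA sequencing was done on 3 libraries of C4-2 cells carrying the vector (the vector libraries) and 3 libraries of C4-2 cells with a CRISPR-Cas9 knockout of CDK12 (the knockout libraries). The libraries held 24660798 to 30732841 reads, of which 16617644 to 21590817 were counted in genes. The labels do not say that replicates were separate cultures or separately edited clones, so p-values measure only the spread between these libraries, which may be technical. Other differences between the vector and knockout lines cannot be told apart from loss of CDK12.

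Knockout library 2 stood apart from the other 5 libraries. Its log2 CPM (library-scaled counts) correlated with theirs across genes at r = 0.916 to 0.950, while the other 5 libraries correlated with each other at 0.977 to 0.990. The first principal component, with 68.1% of the variance, placed it at 101 and the other libraries between -38.8 and 3.78. Its normalisation factor was 0.737, against 1.04 to 1.10 elsewhere. It also had the lowest share of reads outside genes, 3.62% against 5.42% to 7.45%, and the fewest genes with a count when every library was thinned to 16617644 counted reads, 22794 against 24427 to 25322. The edgeR count of changed genes and the gene lists that passed are given below with all 6 libraries and again without this library.

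**Figure D1:**
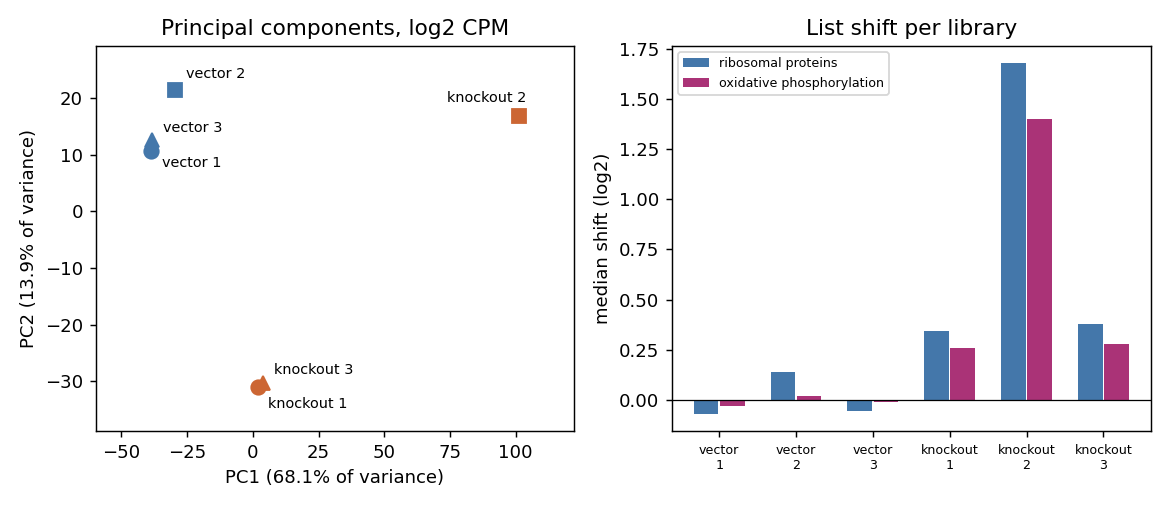
Left, the 6 libraries on principal components 1 and 2 of log2 CPM (axes in component scores, with the percent of variance), vector in blue and knockout in orange. Right, bars give the median shift in log2 CPM of the cytosolic ribosomal protein and nuclear oxidative phosphorylation lists, for a vector library against the other vector libraries and for a knockout library against the vector mean. Knockout library 2 lies at 101 on component 1 and has shifts of 1.68 and 1.40.

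CDK12 RNA was not lower in the knockout libraries. CDK12 (ENSG00000167258.15, chromosome 17, 39461511 to 39564907, GRCh38) stood at 55.1 ± 6.35 CPM in the vector libraries and 58.1 ± 2.35 CPM in the knockout libraries (SD, n = 3 each). The knockout libraries held 60.8, 56.9 and 56.5 CPM and the vector libraries 60.2, 48.0 and 57.1. The log2 fold change was 0.08 ± 0.13 (SE), with an adjusted p of 0.709 in edgeR's quasi-likelihood test. Counts over a whole gene do not show whether its reading frame was disrupted, so this level neither checks nor contradicts the knockout labels. The closely related kinase CDK13 had a log2 fold change of -0.45 ± 0.24 (edgeR adjusted p = 0.281), and -0.24 ± 0.11 without knockout library 2 (edgeR adjusted p = 0.155). For CCNK the value was -1.09 ± 0.70 (edgeR adjusted p = 0.347), with 9.38 ± 1.30 CPM in the vector libraries and 6.33, 0.440 and 6.26 CPM in the knockout libraries. In the fit without knockout library 2, CCNK fell by 0.58 on the log2 scale (edgeR adjusted p = 0.0237, and up to 0.584 over all alternatives).

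Among protein-coding genes with a mean of at least 5 CPM, the strongest rises in the knockout libraries were in 4 neighbouring genes of the UGT2B family on chromosome 4, enzymes that attach glucuronic acid to steroids and other small molecules. UGT2B15 and UGT2B17 are known to inactivate androgens in prostate cells. UGT2B11 went from 0.432 ± 0.108 to 29.6 ± 6.85 CPM (SD, n = 3 each), a log2 fold change of 6.08 ± 0.30 (SE; edgeR adjusted p = 0.000492). UGT2B17 rose by 5.46 ± 0.23 (edgeR adjusted p = 0.000389), UGT2B28 by 5.20 ± 0.23 and UGT2B15 by 4.42 ± 0.32 on the same scale. Together they span 68537184 to 69295050 on chromosome 4 of GRCh38, by the GENCODE 29 annotation. UGT2B10, another gene of this family, singled out after its values were seen, lay below that level with 2 counts over the vector libraries and 146 over the knockout libraries. These genes are near copies of each other, so the split of reads among them is uncertain. IGFBP3, a secreted binding protein of insulin-like growth factors (chromosome 7, 45912245 to 45921874), rose from 3.30 ± 0.776 to 64.6 ± 3.43 CPM, a log2 fold change of 4.29 ± 0.19 (edgeR adjusted p = 0.000389).

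NR2F1, an orphan nuclear receptor, rose by 3.71 ± 0.51 (log2 ± SE, edgeR adjusted p = 0.0347), from 1.05 ± 0.617 to 13.9 ± 4.81 CPM. The neural gene BRINP1 rose by 2.49 ± 0.23 and NES, which encodes the intermediate filament nestin, by 1.99 ± 0.22. DUSP4, a phosphatase of MAP kinases, rose by 2.22 ± 0.17 (edgeR adjusted p = 0.00737). In G protein signalling, the alpha subunit gene GNAI1 rose by 2.04 ± 0.27 and the regulator RGS2 by 2.02 ± 0.17. PGLYRP2, which encodes a peptidoglycan amidase, rose by 2.09 ± 0.32 and had the adjusted p closest to the threshold among these 12 genes, 0.0467 in edgeR.

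Among the genes that fell, PRAG1, which encodes a pseudokinase, went from 34.2 ± 6.53 to 3.37 ± 1.52 CPM, a log2 fold change of -3.33 ± 0.36 (edgeR adjusted p = 0.0199). STARD4, a cholesterol transfer protein gene, changed by -2.16 ± 0.29 and THBS1, which encodes the matrix protein thrombospondin 1, by -1.96 ± 0.29 (edgeR adjusted p = 0.0326 and 0.0440). SLC22A3, an organic cation transporter gene, was the most abundant of the 12 largest falls and went from 346 ± 28.5 to 128 ± 22.8 CPM, a log2 fold change of -1.43 ± 0.17. Receptor genes in this group were IGF1R at -1.35 ± 0.20, the adrenergic receptor gene ADRA2A at -1.29 ± 0.18 and the Hedgehog receptor gene PTCH1 at -1.25 ± 0.15. The cold-sensing channel gene TRPM8, an androgen receptor target, changed by -1.24 ± 0.18. This group also held UTRN (utrophin) at -1.45 ± 0.20, the synaptic gene RIMS1 at -1.41 ± 0.17 and the axonemal dynein gene DNAH5 at -1.34 ± 0.18. In each of the 24 genes that met the rule for the largest rises and falls the 3 knockout libraries lay on the same side of all 3 vector libraries, as that rule required.

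**Figure D2:**
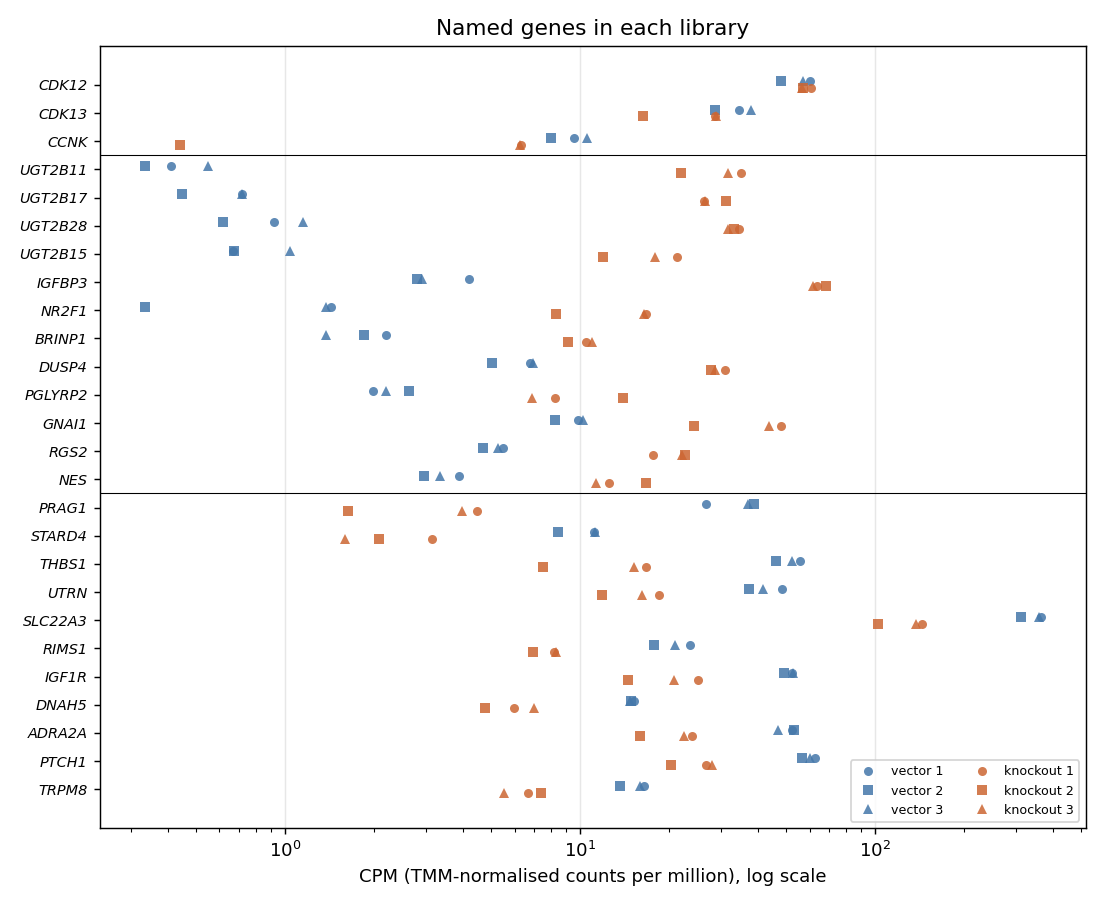
CPM of each named gene in each library (log axis); vector libraries in blue, knockout libraries in orange, with marker shapes for library 1, 2 and 3. The top block holds CDK12, CDK13 and CCNK, the middle block the largest rises and the bottom block the largest falls that are described; UGT2B11 moves from 0.432 to 29.6 CPM on average while CDK12 stays at 55.1 and 58.1.

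With all 6 libraries, 94 of 15783 tested genes passed an adjusted p of 0.05 in edgeR's quasi-likelihood test, 66 higher and 28 lower in the knockout libraries. Of these, 87 changed at least 2-fold, 63 up and 24 down. Without knockout library 2, 3123 of 16339 tested genes passed, 1672 higher and 1451 lower, and 488 of them changed at least 2-fold. All 94 genes were called in both fits with the same direction. Of 3091 genes called without knockout library 2 and tested in both fits, 2922 (94.5%) lay on the called side of the vector mean in that library too. The coefficient of biological variation was 24.2% with it and 8.0% without it. The count fell to 4, 4 and 6 without vector library 1, 2 or 3, and to 13 and 8 without knockout library 1 or 3, and DESeq2's Wald test on all 6 libraries called 980 genes. UGT2B11, UGT2B17, UGT2B28 and IGFBP3 were called whichever library was left out, while of the 24 largest rises and falls 20, 20, 19, 17 and 18 lost their call without vector library 1, 2 or 3 or knockout library 1 or 3, and 0 without knockout library 2. The list members SLC45A3, FOS and TNFAIP2 kept their call without knockout library 2 and lost it when any other library was left out.

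Androgen receptor target genes were lower as a group in the knockout libraries. Of 32 measured members, 2 fell, 0 rose and 30 did not pass the edgeR test over all genes, and adjusted over the list alone 8 fell and 1 rose. Beside TRPM8, the prostate gene SLC45A3 fell, from 655 ± 40.3 to 309 ± 40.0 CPM (log2 -1.08 ± 0.16, edgeR adjusted p = 0.0440, and up to 0.285 with 1 library left out). The list median was -0.29, with a camera adjusted p of 0.000414 and an adjusted p = 0.304 with an estimated correlation. When knockout library 2 was left out, 17 members fell and 1 rose, the median was -0.29 and the camera adjusted p was 5.72e-05 (6.87e-07 to 0.00571 over all alternatives at the preset correlation, and adjusted p = 0.438 with an estimated correlation). Of 21 prostate luminal lineage genes 0 passed in edgeR with all libraries (4 at an unadjusted p under 0.05, and 0 in DESeq2 and limma-voom), and 3 rose and 4 fell without knockout library 2. The lineage factor gene FOXA1 was at 345 ± 26.1 and 235 ± 57.0 CPM (log2 -0.55 ± 0.20, edgeR adjusted p = 0.214). That list had a median of 0.02 (-0.03 without knockout library 2), a camera direction of lower and a camera adjusted p of 0.636.

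Cholesterol and fatty acid synthesis genes were lower as groups. Of 23 cholesterol genes STARD4 alone passed with all libraries, and 3 fell adjusted over the list alone. INSIG1, the sterol sensor partner, had a log2 fold change of -0.73 ± 0.16 (edgeR adjusted p = 0.118). The list median was -0.47 (camera adjusted p = 0.00397, and adjusted p = 0.304 with an estimated correlation). The fit without knockout library 2 had 15 members lower and 1 higher. Of 21 fatty acid genes 0 passed in edgeR over all genes (11 at an unadjusted p under 0.05, 8 in DESeq2 and 0 in limma-voom) and 9 fell adjusted over the list alone. The desaturase genes FADS1 and SCD had log2 fold changes of -0.50 ± 0.12 and -0.69 ± 0.17 (edgeR adjusted p = 0.141 and 0.142). The list median was -0.44 (camera adjusted p = 0.00137, and adjusted p = 0.592 with an estimated correlation), and without knockout library 2 11 members fell and 0 rose.

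Genes of cytosolic ribosomal proteins and of nuclear oxidative phosphorylation subunits were higher as groups, and most so in knockout library 2. The 76 ribosomal protein genes had a median log2 fold change of 0.96, with 0 members past the edgeR threshold over all genes or adjusted over the list alone (48 at an unadjusted p under 0.05, 2 in DESeq2 and 0 in limma-voom). Their median shift over the vector mean was 0.34, 1.68 and 0.38 in knockout libraries 1, 2 and 3. The list's camera adjusted p was 1.46e-10, and adjusted p = 0.641 with an estimated correlation. Without knockout library 2 the median was 0.35 and 66 members rose, among them RPS27A (log2 0.56) and RPS7 (0.44), with 0 lower (camera adjusted p = 3.87e-18, 1.10e-18 to 5.35e-09 over all alternatives at the preset correlation, and adjusted p = 0.438 with an estimated correlation). The 51 oxidative phosphorylation genes had a median of 0.76, 0 members past the edgeR threshold on either adjustment (29 at an unadjusted p under 0.05, 8 in DESeq2 and 0 in limma-voom), and shifts of 0.26, 1.40 and 0.28 (camera adjusted p = 1.97e-06, and adjusted p = 0.641 with an estimated correlation). Without knockout library 2 the median was 0.26, 31 members rose and 1 fell. Examples in that fit were NDUFA4 and COX7A2, subunits of the mitochondrial respiratory chain, at log2 0.51 each. The fry test called neither the ribosomal protein nor the oxidative phosphorylation list with all libraries (adjusted p = 0.269 and 0.222). It called both higher without knockout library 2 (fry adjusted p = 0.0149 and 0.00702). Ribosomal protein genes have many pseudogenes, and reads that map to several places were not counted, so their levels are uncertain.

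Immediate early and NF-kB genes were higher as groups. In the immediate early list of 21 measured genes DUSP4 and FOS rose and 0 fell, and 4 rose adjusted over the list alone. FOS, a subunit of the AP-1 transcription factor, went from 0.725 ± 0.211 to 7.65 ± 2.94 CPM (log2 3.40 ± 0.41, edgeR adjusted p = 0.0253, and up to 0.198 with 1 library left out). JUNB was at 77.5 ± 9.55 and 119 ± 18.1 CPM (edgeR adjusted p = 0.147). The list median was 0.27 (camera adjusted p = 0.00939, and adjusted p = 0.324 with an estimated correlation), the call ended without knockout library 3 (camera adjusted p = 0.0654, 0.000221 to 0.207 over all alternatives at the preset correlation), and 8 members rose without knockout library 2. Of 13 NF-kB and chemokine genes TNFAIP2 rose, from 3.50 ± 0.219 to 10.3 ± 0.823 CPM (log2 1.55 ± 0.17, edgeR adjusted p = 0.0199, and up to 0.199 with 1 library left out), and adjusted over the list alone 5 rose and 1 fell. The NF-kB subunit gene RELB had a log2 fold change of 1.03 ± 0.23 (edgeR adjusted p = 0.118). The list median was 0.43 (camera adjusted p = 0.00948, and adjusted p = 0.304 with an estimated correlation), and the call ended without knockout library 1 or 3 (camera adjusted p = 0.0682 and 0.164, 0.00138 to 0.458 over all alternatives at the preset correlation). With knockout library 2 left out, 6 members rose and 1 fell.

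Replication-dependent histone genes were lower as a group. Their transcripts end in a stem-loop in place of a poly(A) tail and are made mainly in S phase. Of 22 measured genes 0 passed in edgeR over all genes or adjusted over the list alone (11 at an unadjusted p under 0.05, 4 in DESeq2 and 0 in limma-voom), and the median was -0.40 (camera adjusted p = 0.000732, and adjusted p = 0.304 with an estimated correlation). H2BC12 was at 262 ± 15.6 and 176 ± 27.5 CPM (log2 -0.57 ± 0.15, edgeR adjusted p = 0.161) and the linker histone gene H1-4 at 7.93 ± 1.68 and 3.87 ± 0.865 CPM. Leaving knockout library 2 out, 15 of 25 measured members fell and 0 rose. Many histone genes are near copies, so reads shared among them were not counted. The E2F and G1/S list (39 genes, median -0.14, camera adjusted p = 0.438) and the G2/M and mitosis list (35 genes, median -0.17, camera adjusted p = 0.277) had 0 edgeR calls. In these lists 4 and 9 genes had an unadjusted p under 0.05, DESeq2 called 1 and 0, and limma-voom 0 and 0. With knockout library 2 left out, the medians were -0.03 and -0.08, 3 E2F and G1/S genes rose and 0 fell, and 3 G2/M and mitosis genes rose and 6 fell.

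Homologous recombination and Fanconi genes, whose transcription CDK12 is known to sustain, did not pass as a group. Of 39 measured members 0 passed in edgeR over all genes or adjusted over the list alone, 6 had an unadjusted p under 0.05 and DESeq2 called 1 and limma-voom 0. The list median was -0.18 (camera adjusted p = 0.182), -0.06 without knockout library 2 and -0.05 after a correction for transcript length and GC content. That correction removes any trend with transcript length, also one due to the knockout, so the last value cannot speak against such an effect. NBN, a subunit of the double-strand break sensor complex, had a log2 fold change of -0.52 ± 0.14 (edgeR adjusted p = 0.160). FANCA was at 69.0 ± 4.10 and 45.0 ± 11.1 CPM, and RAD51C at 62.2 ± 2.22 and 83.5 ± 14.6 CPM. In the fit without knockout library 2 3 members fell, NBN, FANCF and FANCA, and RAD51C was 1 of 2 that rose (log2 0.27, edgeR adjusted p = 0.0179, 0.0112 to 0.491 over all alternatives). The list of CDK12 and transcription elongation kinases (19 genes, median -0.13, camera adjusted p = 0.482) had 0 members with an edgeR call, an unadjusted p under 0.05, or a DESeq2 or limma-voom call. POLR2A, the largest subunit of RNA polymerase II, was at 72.7 ± 7.69 and 37.2 ± 22.6 CPM (edgeR adjusted p = 0.261). In the fit without knockout library 2, 3 of these genes fell and the list median was -0.07. POLR2A was among the 3 (log2 -0.56, edgeR adjusted p = 0.00158, and up to 0.522 over all alternatives). The splicing and 3 prime end processing list (39 genes) had a median of -0.05 and a camera adjusted p of 0.668, with 0 edgeR calls, 2 genes at an unadjusted p under 0.05 and 0 calls by DESeq2 and limma-voom, and without knockout library 2 the median was 0.02 and 2 genes rose.

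Marker lists of other cell types did not pass camera with all libraries. Summed over each list, knockout libraries 1, 2 and 3 held 5.81, 11.4 and 6.05 CPM of basal epithelial genes (4.25 ± 0.554 in the vector libraries), 71.8, 114 and 74.4 CPM of neuroendocrine genes (72.0 ± 6.72) and 45.6, 54.1 and 49.7 CPM of fibroblast and stromal genes (35.4 ± 1.02). Leukocyte genes summed to 167, 186 and 151 CPM (193 ± 8.09), mostly LCP1, and endothelial genes to 12.3, 16.1 and 16.2 CPM (10.3 ± 0.400). The camera adjusted p was 0.153 for the basal list (median 0.79 over 3 measured genes), 0.973 for the neuroendocrine list (0.42 over 6), 0.371 for the fibroblast list (0.45 over 6), 0.636 for the leukocyte list (-0.13 over 4) and 0.370 for the endothelial list (0.53 over 4). The basal list passed without vector library 1 or 3 or knockout library 1 (camera adjusted p = 0.0356, 0.0287 and 0.0402, up to 0.781 over all alternatives at the preset correlation but the stricter filter, which left no value). The fry test called the neuroendocrine list lower (adjusted p = 0.00491). In the fit without knockout library 2, 2 neuroendocrine genes rose and 2 fell, 1 fibroblast and 1 leukocyte gene rose and 1 of each fell, and 2 endothelial genes rose, with medians of 0.25, 0.50, -0.32 and 0.51 for these lists. Among 10 mesenchymal genes THBS1 fell and 0 rose (median 0.22, camera adjusted p = 0.636), and without knockout library 2 3 rose and 1 fell. VIM, which encodes vimentin, had a log2 fold change of 1.16 ± 0.24 (edgeR adjusted p = 0.106). The neuroendocrine and fibroblast lists had medians above 0 and mean log2 fold changes of -0.71 and -0.70, each lowered by 1 gene at 0 counts in the knockout libraries, and their medians were the same with that gene at its lower bound.

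**Figure D3:**
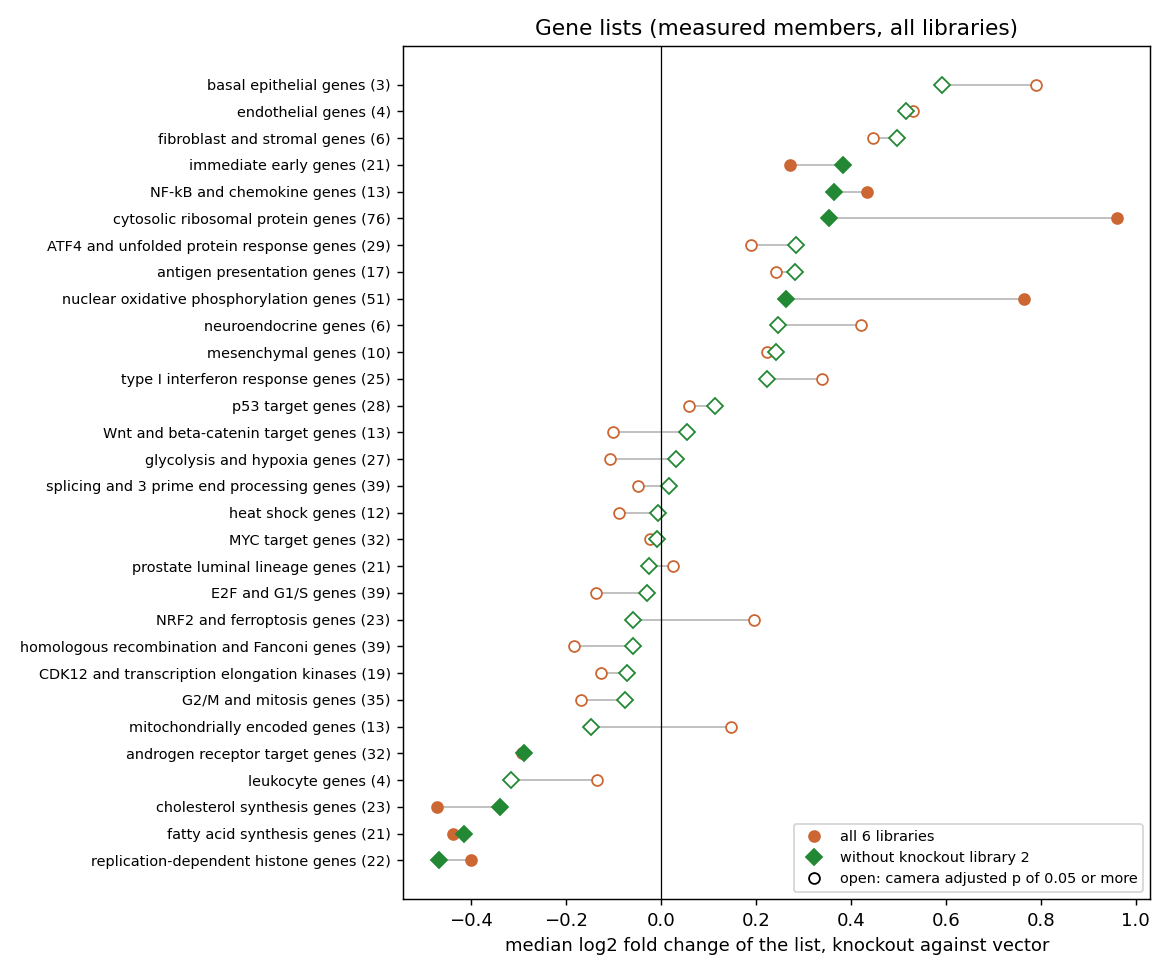
Median log2 fold change of each gene list, knockout against vector, with all 6 libraries (circles) and without knockout library 2 (diamonds); filled symbols have a camera adjusted p under 0.05 at the preset correlation and the number of measured genes is in parentheses. The ribosomal protein list moves from 0.96 to 0.35 and the androgen receptor target list stays at -0.29.

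Longer genes tended to have lower fold changes. Among 15250 tested genes with an annotated span, log2 span and log2 fold change had a Spearman rho of -0.27 across genes, which are not independent replicates. Exonic length had a rho of -0.30 and GC content one of 0.27, so the trend was not particular to gene span. The median log2 fold change went from 0.27 in the shortest quintile of genes (spans of 0.0530 to 5.48 kb) over 0.17, 0.02 and -0.12 to -0.19 in the longest (82.4 to 2305 kb). Without knockout library 2 rho was -0.15 with span and -0.18 with exonic length, and the medians ran from 0.08 to -0.11. UTRN, DNAH5, RIMS1 and IGF1R are among the long genes that fell, while GNAI1 and BRINP1 are long genes that rose.

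Tested over libraries, this trend did not separate the groups. The mean log2 CPM of the longest quintile exceeded that of the shortest by 1.54 ± 0.13 in the vector libraries and 1.19 ± 0.38 in the knockout libraries (SD, n = 3 each). Knockout library 2 was at 0.75 and the other 5 libraries at 1.36 to 1.64. The difference of -0.35 had an exact permutation p of 0.2 (two-sided), where 3 libraries against 3 allow no p under 0.1. Each library's own rho with span set a vector library against the other vector libraries and a knockout library against the vector mean. It was 0.19, -0.27 and 0.12 in vector libraries 1, 2 and 3 and -0.14, -0.30 and -0.21 in knockout libraries 1, 2 and 3. The value of vector library 2 lay within the range of the knockout libraries, although the groups had different references.

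**Figure D4:**
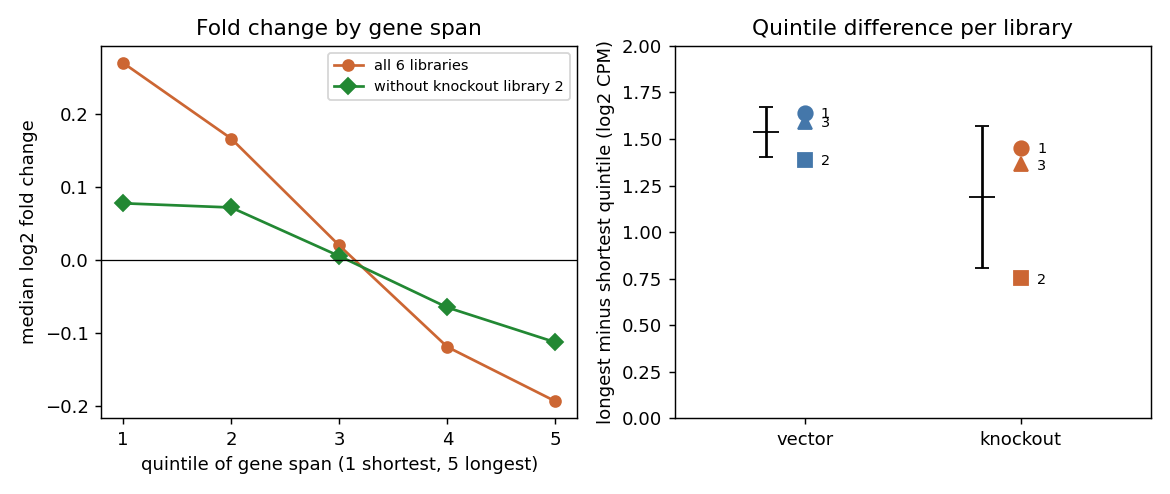
Left, median log2 fold change in 5 quintiles of gene span (1 shortest, 5 longest) with all 6 libraries (orange) and without knockout library 2 (green). Right, longest minus shortest quintile in mean log2 CPM for each library, with mean and SD per group in black; vector libraries average 1.54 and knockout libraries 1.19.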

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

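Of the tests in this part, the length and GC correction, the interval of the marker lists, the check for a mislabelled library and the splits of the samples were chosen only after the result was seen.

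Reads that fall in more than 1 gene lie outside the gene counts. Their share was 11.6%, 11.2% and 11.1% in vector libraries 1 to 3 and 12.2%, 14.4% and 12.2% in knockout libraries 1 to 3, with a mean of 12.9% over the knockout libraries, so every knockout library lay above every vector library.

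Knockout library 2 stood apart from the other knockout libraries, with an SD over genes of 0.77 (log2) against their mean, compared with at most 0.22 for a vector library against the other vector libraries. A trend over transcript length and GC content is argued against as the whole cause: with it removed from every library, that SD was 0.66 and still 3.52 times the largest SD of a vector library (3.55 times before). A vector library under a knockout label is argued against because 94.5% of the genes called without this library lay on the called side in it. RNA from another cell type cannot be told apart from other sources: of 5 marker lists the basal list had the highest summed CPM against the other knockout libraries, 1.92 times (95% counting interval 1.58 to 2.34, which holds the bound of 2 set beforehand, while the use of an interval was chosen later), its genes lie near the floor, and the neuroendocrine list was at 1.56 times (1.48 to 1.66). Differences in RNA quality, culture or clone stay open and untested: this library had the lowest share of reads outside genes (3.62%), the fewest genes at equal depth (22794) and the smallest excess of long over short genes (0.75 in log2 CPM), but no label tells these sources from each other.

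Of the 10 ways to split the 6 libraries into groups of 3, 1 split, the real one, gave 94 genes, and the highest of the others gave 0. With 10 splits no share under 0.05 can be reached.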

How the results depend on the processing

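The length and GC corrections and the sample weights were chosen after seeing the data. The count of changed genes, 94 with all libraries, was 12 at an adjusted p under 0.01, 363 with no filter (32640 genes tested), 980 with DESeq2 and 4 to 3123 when 1 library was left out, the highest without knockout library 2. Correction for transcript length and GC gave 160, the same without knockout library 2 gave 3120, and voom with sample weights, which gave that library a weight of 0.0811, called 3839. With the replicate block the count was 5, and 19 of the 24 largest rises and falls and all 6 called list members lost their call. Whether replicate numbers pair the libraries cannot be told. Deviations from the group means of same-numbered libraries correlated at 0.135, 0.194 and 0.0841, not all over 0.1. Every library correlated best with its own number in the other group. These matches are not independent, because deviations sum to 0 within a group. Vector library 3 correlated at 0.0841 with knockout library 3 and at 0.0762 with knockout library 1, so the matches do not decide on pairing. Other scaling factors gave 95 and 96 genes, the stricter filter 66 and limma-voom 105. The number of lists passing, 8, stayed between 6 and 9 except with an estimated correlation, where it was 0. For the cholesterol, NF-kB and histone lists the estimate with all libraries (-0.029, -0.034 and -0.031) lay below the preset 0.01. A higher correlation was therefore not why these lists lost their call. The CDK12 log2 fold change ran from -0.02 to 0.35 and was not called under any alternative run. The Spearman correlation of gene length and fold change, -0.27, was -0.0615 with no filter, -0.398 with the stricter filter, -0.0551 after the correction and -0.0271 after it without knockout library 2, and -0.291 to -0.155 when 1 library was left out. The correction removes a length trend by construction, and elsewhere the cause was not tested.

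No list or named gene that was called changed direction under any alternative run. In 24 of 479 comparisons of a list the camera direction differed while it was called in neither. The antigen presentation list passed with no filter (camera adjusted p = 0.0487, up to 0.836 over its alternatives at the preset correlation), the NF-kB list lost its call with no filter and the stricter filter (0.458 and 0.153), and the immediate early list with the stricter filter and the length and GC correction (0.207 and 0.113). Depth limits genes near the floor, such as the UGT2B genes in the vector libraries.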

Other observations

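The length and GC correction and the 2 tests on the UGT2B genes were chosen only after the result was seen. The p53, ATF4, interferon and antigen presentation lists did not pass camera with all libraries. The fry test called the interferon list higher with all libraries (adjusted p = 0.0208) and not without knockout library 2 (0.0527), and called the p53, ATF4 and antigen presentation lists higher without knockout library 2 (adjusted p = 0.0454, 0.0149 and 0.0418) and not with all libraries (0.222, 0.109 and 0.181). GDF15, NLRC5 and MT-ND4L kept their edgeR call without knockout library 2 and lost it when any other library was left out, with adjusted p up to 0.316, 0.279 and 0.213. Of 28 p53 target genes GDF15, a stress-induced secreted factor, rose from 178 ± 4.83 to 394 ± 80.5 CPM (log2 1.15 ± 0.17, edgeR adjusted p = 0.0468), and the list had a median of 0.06 (camera adjusted p = 0.371). Without knockout library 2, 7 p53 targets rose and 1 fell (median 0.11), BAX and PHLDA3 among the risers at log2 0.63 and 0.69. Of 29 genes of the ATF4 and unfolded protein response, 0 passed in edgeR over all genes (14 at an unadjusted p under 0.05, 10 in DESeq2, 1 in limma-voom), and adjusted over the list alone 7 rose and 4 fell (median 0.19, camera adjusted p = 0.371). DDIT4, TRIB3 and CHAC1 had log2 fold changes of 0.87, 0.78 and 1.00 and the chaperone gene DNAJC3 -0.79, and without knockout library 2 15 members rose and 8 fell (median 0.28). Of 17 antigen presentation genes NLRC5, a transactivator of MHC class I genes, rose from 3.42 ± 0.133 to 8.01 ± 0.883 CPM (edgeR adjusted p = 0.0431; median 0.24, camera adjusted p = 0.464), and 3 members rose and 2 fell without knockout library 2. Of 25 interferon response genes 0 passed in edgeR (8 at an unadjusted p under 0.05, 4 in DESeq2, 0 in limma-voom), with IFI6 at log2 1.25 and MX1 at -0.63 (median 0.34, camera adjusted p = 0.264). Of the interferon response genes 5 rose and 2 fell without knockout library 2 (median 0.22).

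Of 13 mitochondrially encoded genes MT-ND4L fell, from 212 ± 23.3 to 90.8 ± 13.6 CPM (edgeR adjusted p = 0.0316, and up to 0.213 with 1 library left out), and it overlaps MT-ND4, so its count leaves out shared reads. That list had a median of 0.15 (-0.15 without knockout library 2), a camera direction of lower and a camera adjusted p of 0.611, and it passed as lower after the length and GC correction without knockout library 2 (camera adjusted p = 0.0306, up to 0.996 over all alternatives at the preset correlation). The NRF2 and ferroptosis list (23 genes, median 0.19, camera adjusted p = 0.636) held AKR1C2 at log2 2.16 and GCLC at -0.83, 0 edgeR calls, 8 genes at an unadjusted p under 0.05, 6 DESeq2 calls and 0 in limma-voom, and without knockout library 2 the median was -0.06, 6 members rose and 6 fell. The Wnt target (13 genes, median -0.10, camera adjusted p = 0.438), MYC target (32, -0.02, 0.636), glycolysis and hypoxia (27, -0.11, 0.636) and heat shock (12, -0.09, 0.824) lists did not pass. The MYC and heat shock lists had means of 0.04 and 0.15, against medians below 0. In these 4 lists edgeR called 0 genes, with 3, 7, 1 and 2 at an unadjusted p under 0.05, 2, 1, 0 and 0 calls by DESeq2 and 0 by limma-voom. In the order above, 1, 5, 1 and 2 of their genes rose and 1, 6, 2 and 0 fell without knockout library 2, with medians of 0.05, -0.01, 0.03 and -0.01.

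Genes with 0 counts in all 3 knockout libraries were sought only among genes called with all libraries and tested list members, so others may exist. Those given here were singled out after their values were seen. FBN2 held 58 counts over the vector libraries and was at least 19.6-fold lower, and the small nuclear RNA pseudogene RNU6-660P held 1012 and was at least 342-fold lower (floor of 3 counts over the group). COL1A2 (52 counts, at least 17.6-fold lower) and PEG10 (45 counts, at least 15.2-fold lower) lie near each other on chromosome 7, 94394561 to 94431232 and 94656325 to 94669695, and did not pass with all libraries (edgeR adjusted p = 0.0743 and 0.0540) but passed without knockout library 2 (0.000704 and 0.000866, with ranges of 6.17e-05 to 0.340 and 2.32e-05 to 0.308 over all alternatives but the stricter filter, which does not test them). CASD1, which lies between them, had a log2 fold change of -0.42 ± 0.25 (edgeR adjusted p = 0.314).

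The 4 named UGT2B genes on chromosome 4 were higher in every knockout library than in every vector library. A copy number gain of the surrounding region is argued against: 20 tested genes within 5 Mb had a median log2 fold change of -0.23 (quartiles -0.43 and -0.02), although the tested neighbour nearest to the cluster, TMPRSS11E (68447449 to 68497604), was the highest at 0.99 (edgeR adjusted p = 0.204, and 0.0201 without knockout library 2). Whether reads of 1 gene were assigned to its paralogs cannot be told apart from separate rises: the ratio of UGT2B11 to UGT2B28 counts differed 1.90-fold between the groups, with an interval of 1.07 to 3.45 (outer bounds of 95% counting intervals) that holds the bound of 1.5, a requirement on the interval set after the ratio was seen. The ratio of UGT2B15 to UGT2B28 moved the other way, from 0.880 (0.573 to 1.35) in the vector libraries to 0.529 (0.489 to 0.571) in the knockout libraries. A gain of this cluster alone or with its nearest neighbour and an effect of the knockout on these genes stay open and were not tested. Another difference between the vector and knockout lines cannot be told apart from these.

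Ribosomal protein and oxidative phosphorylation genes were higher in the knockout libraries. A transcript length and GC trend is argued against as the whole cause of the raised medians. Without knockout library 2 they were 0.29 and 0.19 after its removal, against 0.35 and 0.26 before. Camera at the preset correlation still called both lists higher with all libraries and without knockout library 2 (larger adjusted p = 5.35e-09 and 2.00e-05). These calls hold only at the preset of 0.01. The correlation estimated before the removal was 0.862 and 0.543 with all libraries, and 0.403 and -0.00124 without knockout library 2. The spread between vector libraries was smaller, with a largest vector shift of 0.406 and 0.116 of the smallest knockout shift. The knockout libraries themselves spread more, with shifts of 0.34, 1.68 and 0.38 for the first list and 0.26, 1.40 and 0.28 for the second. A comparison with the vector libraries alone can therefore not decide on variation between libraries of 1 group. With an estimated correlation neither list passed camera after the correction, with all libraries (adjusted p = 0.581 and 0.548) or without knockout library 2 (adjusted p = 0.376 and 0.150). A shared shift of libraries, such as from RNA quality or growth state, stays open beside an effect of the knockout and was not tested. Another difference between the vector and knockout lines cannot be told apart from these.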
